A study of Mus musculus with 8 samples.

How the data were processed

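RNA from mouse intestinal epithelial cells was sequenced in 8 libraries, 4 from control animals that carry the Villin-Cre driver alone (WT) and 4 from animals that carry Villin-Cre with a floxed Rictor allele (cKO). Villin-Cre expresses Cre recombinase in the intestinal epithelium, so that a floxed gene is deleted there. Per the labels' protocols, RNA quality was checked on a Bioanalyzer, sequencing was on an Illumina NovaSeq instrument, and reads were processed with Hisat2, a spliced aligner, followed by Stringtie, a transcript assembler. The software versions, the genome build, the counting program, its treatment of strand and of reads with several matches, and the library kit are not given in the sources used here. The intestinal segment, the way epithelial cells were isolated, the exons flanked by loxP sites and the sex of the animals are likewise not given in the sources used here. The labels do not say that each library came from a separate mouse. The p-values measure the spread between these libraries, part of which may be technical.

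The authors deposited a table of whole-number read counts per gene with no normalization and a table of FPKM (fragments scaled by gene length and library total) for the same 54139 genes, including 338 loci that carry no Ensembl identifier. The library total implied by the FPKM, as a median over well-counted genes, was between 0.955 and 1.06 of the column total of counts. The lowest ratio was in WT library 3 and the highest in cKO library 2, whose TMM factors were 0.946 and 1.04. The FPKM may therefore rest on normalized totals. Coordinates are those of the deposited table. Of its identifiers 53620 are in the GENCODE M21 annotation of mouse build GRCm38, and 52056 of these (97.1%) have identical chromosome, start and end there, so coordinates are given on that build.

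Total counts ran from 15110451 in cKO library 4 to 18708335 in WT library 1. No pair of libraries agreed within sampling noise, the lowest chi-square per degree of freedom over genes being 10.7. Counts were tested with the quasi-likelihood F-test of edgeR (version 4.0.16 in R 4.3.3, robust fit) with TMM factors, the default filter on low counts (14701 genes kept), genotype as the single term, and Benjamini-Hochberg adjustment over all genes tested at a threshold of 0.05. Fold changes are cKO over WT. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic, and its median over genes was 0.17. CPM values, counts relative to the total of the library, use TMM-scaled totals and are given as mean ± SD. Intervals of single libraries are exact Poisson intervals at 95% and cover counting error only.

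Gene lists for pathways and cell types, 48 in all, were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, and 43 had the 5 tested members required. Camera with an estimated correlation and fry, a test of whether the genes of a list move on balance in 1 direction, were run as alternatives. The score of a list in a library is the median over its members of the log2 CPM (prior count 2) centred on the mean of the 8 libraries.

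The lists, tests and the rule for naming genes were fixed before the data were examined. The rule names Rictor and the mTOR complex list, then up to 12 called genes in each direction by fold change, replaced by the 5 genes with the smallest p in each direction if under 10 genes pass. It adds up to 4 members with the smallest adjusted p of each list past the threshold and up to 2 called members of each other list. Predicted, clone-named and receptor-segment genes are left out of the up to 12 called genes. The replacement, which was the branch used here, did not apply that exclusion. Some genes that the rule names are not reported here. A gene named outside the rule is described as chosen after its values were seen.

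Alternatives fixed beforehand were DESeq2-style and upper-quartile factors, no filter, a filter of CPM 1 in 4 libraries, leaving out each library, the replicate number as a block, limma voom with sample quality weights, the DESeq2 (version 1.42.0) Wald test, and limma on log2(FPKM + 0.1) with and without a mean FPKM minimum of 0.5 and on log2(FPKM + 1). After seeing the data, 2 more were added: leaving out WT library 3 and cKO library 3 together, and offsets that remove a spline trend on transcript length and GC content from each library (GC known for 98.3% of tested genes).

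The edgeR and camera steps were tested on simulated data drawn from the means and library sizes of these 8 libraries for the same 14701 genes. At an adjusted p threshold of 0.05, edgeR called 13.4% of the 67 genes changed 1.5-fold, 59.7% of the 67 changed 2-fold and 89.4% of the 66 changed 4-fold. Of its calls 6.90% were unchanged genes. Where fewer genes change, the adjusted threshold is harder to pass and these shares are lower. A list raised 1.3-fold had a camera adjusted p of 1.7e-18 and 0 other lists were called. The simulated genes varied independently, unlike real ones.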

Results

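Gene expression was measured by RNA sequencing in intestinal epithelial cells of mice, in 4 WT libraries (Villin-Cre) and 4 cKO libraries (Rictor floxed with Villin-Cre). Rictor is the subunit that defines mTOR complex 2, a kinase complex that phosphorylates Akt, SGK1 and protein kinase C. The comparison asks which transcripts differ when Rictor is deleted from the epithelium. Total counts ran from 15982538 to 18708335 in WT and from 15110451 to 18351748 in cKO. Between 21346 and 21727 genes were detected per library, and mitochondrial genes took from 5.28% to 7.71% of counts.

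Rictor (ENSMUSG00000050310, chromosome 15, 6708379 to 6800401, plus strand, protein coding) was measured first, as the targeted gene. Its level was 48.2 ± 7.51 CPM in WT and 32.8 ± 9.24 CPM in cKO (SD, n = 4 each). The 4 WT libraries had 41.7, 42.4, 57.3 and 51.4 CPM, and cKO libraries 1 to 4 had 30.4, 39.6, 20.8 and 40.6 CPM. The cKO level was 68.1% of WT (95% interval 50.1 to 92.6), a log2 fold change of -0.55 ± 0.20 (SE). All 4 cKO libraries lay below all 4 WT libraries, and the exact two-sided permutation p of 0.0286 is the smallest that 4 against 4 can give. The edgeR p was 0.0190 unadjusted and 0.921 adjusted over all genes. The lowest value was in cKO library 3, which stood apart from the other libraries and had a strong trend with transcript GC content and length. With that trend removed from each library the log2 fold change was -0.41 ± 0.13 (edgeR adjusted p = 0.999, and 0.00898 unadjusted), without cKO library 3 and WT library 3 it was -0.29, and with sample quality weights -0.25. The lowest WT library exceeded the highest cKO library 1.03-fold, with a counting interval of 0.925 to 1.14, so those libraries were not separable at this depth. Counts per gene include exons outside the deleted part, so they do not measure the intact transcript.

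Of the 11 genes of the mTOR complexes measured, Rictor included, 7 had higher and 4 lower point estimates in cKO, and none passed the adjusted threshold of edgeR or did so adjusted over the list alone. Deptor, an inhibitor that binds both complexes, had a log2 fold change of -0.52 ± 0.19 (SE), from 157 ± 19.9 to 110 ± 31.5 CPM (SD, n = 4 each), with an edgeR adjusted p of 0.921. Mtor itself was at 67.1 ± 1.47 CPM in WT and 67.4 ± 6.65 CPM in cKO. Mapkap1, a core subunit of mTOR complex 2, had a log2 fold change of -0.04 ± 0.09. The shared subunit Mlst8 was at -0.021 ± 0.12 and the mTOR complex 1 subunit Rptor at 0.16 ± 0.13. Akt1s1, Tti1, Telo2, Prr5 and Prr5l lay between 0.10 and 0.42. These small values were not stable. Without cKO library 3 Prr5l was at 0.16, Prr5 at 0.081, Rptor at 0.034 and Akt1s1 at 0.014, and without WT library 3 Prr5l was at 0.65, Telo2 at 0.055, Tti1 at 0.098 and Akt1s1 at 0.092. Prr5l was at 0.27 without WT library 1 and 0.69 without cKO library 2, Telo2 at 0.055 and 0.16 without cKO library 2 or 4, and Tti1 at 0.25 without cKO library 1. Without both libraries 3 Deptor was at -0.28, and Mapkap1 ranged from -0.062 to -0.0046 without 1 library. The signs of Mtor, Mlst8 and Akt1s1 flipped in some alternative fits.

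Across the transcriptome 2 genes passed the adjusted threshold, both changed more than 2-fold. Popdc3, a membrane protein of the Popeye domain family that binds cAMP (ENSMUSG00000019848, chromosome 10, 45178098 to 45318452), rose from 0.362 ± 0.131 CPM in WT to 4.57 ± 1.68 CPM in cKO (SD, n = 4 each). Its log2 fold change was 3.64 ± 0.37 (SE; edgeR adjusted p = 0.0112), and it was higher in all 4 cKO libraries than in any WT library. Ces1f, a carboxylesterase (ENSMUSG00000031725, chromosome 8, 93256236 to 93279747), fell from 116 ± 7.87 to 50.2 ± 10.6 CPM, a log2 fold change of -1.21 ± 0.15 (edgeR adjusted p = 0.0358). Ces1f belongs to a cluster of similar genes among which reads can be shared. Both calls were lost when any of WT libraries 1, 2 or 3 was left out, with Popdc3 at 3.59, 3.60 and 3.50 and Ces1f at -1.23, -1.22 and -1.16. Ces1f alone was also lost without WT library 4 or cKO library 1 or 4, at -1.20, -1.22 and -1.20. Neither passed in limma on log2(FPKM + 0.1), with Popdc3 at 3.03 and Ces1f at -1.22, or on log2(FPKM + 1), at 1.41 and -1.17, a scale that understates the change of low genes.

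**Figure D1:**
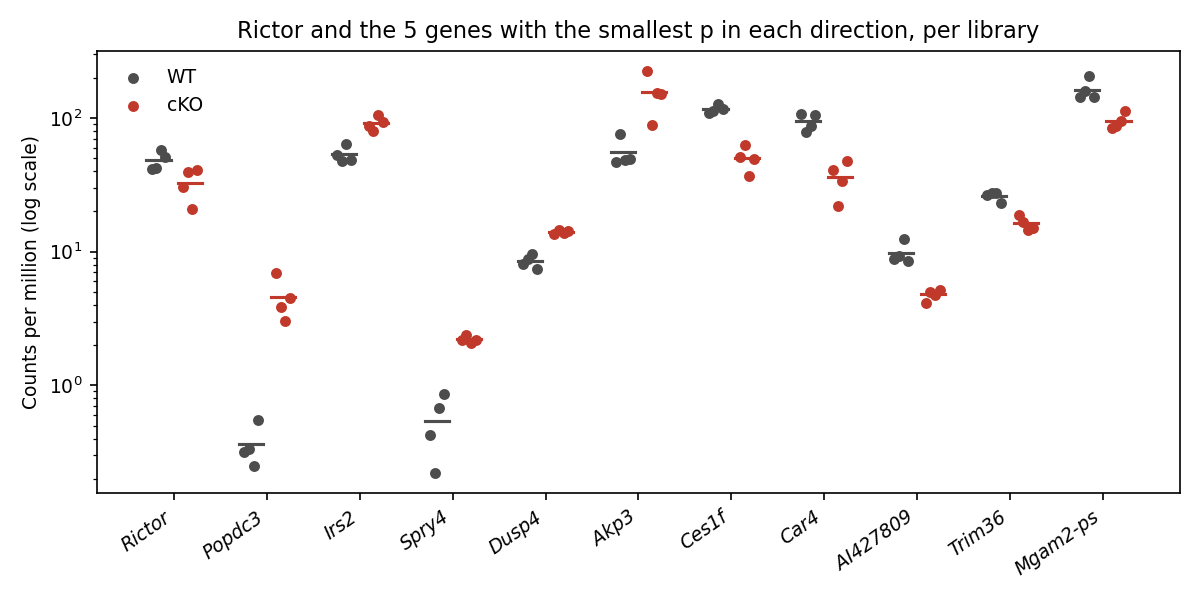
CPM on a log scale for Rictor and for the 5 genes with the smallest p in each direction. Each point is a library (4 WT in grey, 4 cKO in red) and each bar a group mean; Popdc3 lies at 0.247 to 0.550 in WT and at 3.03 to 6.93 in cKO.

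The genes with the next smallest p did not pass the adjusted threshold of edgeR with all libraries and the default filter, although WT and cKO libraries did not overlap for any of them. Irs2, an adaptor of the insulin and IGF1 receptors and a FoxO target, was at 53.4 ± 7.48 CPM in WT and 91.4 ± 10.8 CPM in cKO, a log2 fold change of 0.77 ± 0.13 (edgeR adjusted p = 0.276). Car4, a membrane-bound carbonic anhydrase, was at 94.2 ± 14.1 and 36.0 ± 11.2 CPM, a log2 fold change of -1.39 ± 0.22 (edgeR adjusted p = 0.276). Spry4 and Dusp4, feedback inhibitors of ERK signalling, had log2 fold changes of 2.02 ± 0.37 and 0.73 ± 0.14, with Spry4 at 0.545 ± 0.280 CPM in WT and 2.20 ± 0.118 CPM in cKO. Akp3, an intestinal alkaline phosphatase with close paralogs, was at 55.4 ± 14.0 and 155 ± 55.7 CPM. On the lower side were Trim36, a ubiquitin ligase, at -0.68 ± 0.13, the long noncoding RNA AI427809 at -1.03 ± 0.18, and Mgam2-ps, a pseudogene that can share reads with its parent family, at -0.78 ± 0.14. Each of these last 6 had an edgeR adjusted p of 0.374. Without a filter on low counts, edgeR called Irs2 (adjusted p = 0.0111), Spry4 (0.0329) and Mgam2-ps (0.0153), and without cKO library 2 it called Akp3 (0.0415). With sample quality weights limma called Irs2 (adjusted p = 0.0116), Spry4, Dusp4 and Trim36 (0.0477 each), and without both libraries 3 edgeR called Irs2 (adjusted p = 0.0432). Over all alternatives, DESeq2 included, the adjusted p ran from 0.000468 to 0.770 for Irs2, from 0.00173 to 0.897 for Spry4, from 0.00261 to 0.897 for Dusp4 and from 0.00249 to 0.897 for Trim36. It ran from 0.00220 to 0.846 for Mgam2-ps and from 3.00e-05 to 0.897 for Akp3.

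In all, 573 of 14701 genes (3.90%) had an edgeR p under 0.05 before adjustment, 269 higher and 304 lower in cKO. That is below the share of 0.05 that chance alone gives. Of the 35 ways to split the 8 libraries into 4 and 4, 16 gave as many, the real one included. The groups did not overlap for 472 genes (3.21%), against 2.86% by chance for 4 against 4. The DESeq2 Wald test called 41 genes, 21 higher and 20 lower, including both edgeR calls, Irs2, Car4, Akp3, Spry4, Dusp4, Trim36, AI427809 and Mgam2-ps. The biological coefficient of variation was 22.0%.

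Among the 43 lists tested, 6 passed camera at its preset correlation, 5 higher and 1 lower in cKO. With an estimated correlation 0 lists passed, each of the 6 having an adjusted p of 0.982, and 0 passed by fry, with adjusted p = 0.973. Each of the 35 ways to split the 8 libraries into 4 and 4 gave at least 6 lists past camera at its preset correlation, so the counts below describe these libraries.

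Genes of cholesterol synthesis had higher point estimates in cKO for 23 of 25 members, with a median log2 fold change of 0.21 (camera adjusted p = 2.04e-05, and 0.982 with an estimated correlation). Lss, the lanosterol synthase, had 0.42 ± 0.16 (SE), Cyp51, the lanosterol demethylase, 0.37 ± 0.17, and Nsdhl 0.30 ± 0.13. None passed singly. Cyp51 overlaps Akap9 on the opposite strand. The list scores were 0.33 and 0.38 in cKO libraries 1 and 3 but -0.011 and -0.20 in cKO libraries 2 and 4, against -0.29 to 0.094 in WT. In cKO the T cell list below split the same way, at 0.53 and 1.05 in libraries 1 and 3 against -0.42 and -0.44 in libraries 2 and 4, as did glycolysis genes, at 0.22 and 0.37 against -0.20 and -0.16. In WT library 2 the T cell score was lowest (-0.98) and the cholesterol score highest. Library 3 of cKO stood apart from the others, and without both libraries 3 Lss was at 0.27 and Nsdhl at 0.16. The mean of 0.22 was 0.14 without cKO library 1 or 3, and the call was lost with sample quality weights, at 0.052.

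Wnt target genes were higher for 15 of 16 members, with a median of 0.25 (camera adjusted p = 2.04e-05, and 0.982 with an estimated correlation). Myc, a growth-promoting transcription factor, had 0.35 ± 0.10 and Tcf7, a nuclear effector of Wnt signalling, 0.52 ± 0.15, and both passed when adjusted over the list alone. The stem cell factor Ascl2 had 0.42 ± 0.19 and Dkk3 0.96 ± 0.34 at 1.21 ± 0.319 CPM in WT and 2.37 ± 1.03 CPM in cKO. Dkk3 was highest in cKO library 2 and its log2 fold change without that library was 0.62, while Ascl2 was at 0.28 without both libraries 3. The list scores were 0.13 to 0.32 in cKO libraries 2, 3 and 4 but -0.21 in cKO library 1, against -0.20 to -0.038 in WT. Enterocyte scores were highest in WT library 3 (0.83) and cKO library 1 (0.35), which had the lowest Wnt scores of their groups. Across groups this did not hold, as cKO library 3 (0.051) lay above WT libraries 1, 2 and 4 (-0.44 to -0.20). The share of enterocytes was not separated from the Wnt list. Crypt base stem cell markers were higher for 10 and lower for 8 of 18 members (camera adjusted p = 0.0711, and 0.982 with an estimated correlation), and their score was likewise -0.32 in cKO library 1 and 0.10 to 0.26 in the other cKO libraries, against -0.18 to 0.057 in WT. Of these 18 markers 5 are also in the Wnt list. The other 13, set apart after the scores were seen, had 5 higher and 8 lower members and a score of -0.34 in cKO library 1 and 0.14 to 0.25 in the other cKO libraries.

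Enteroendocrine markers were higher for 22 of 28 members, with a median of 0.28 (camera adjusted p = 6.99e-05, and 0.982 with an estimated correlation). Sst, the hormone of D cells, had a log2 fold change of 0.75 ± 0.16, from 36.1 ± 3.57 to 60.5 ± 13.8 CPM, and passed when adjusted over the list alone, with an edgeR adjusted p of 0.489 over all genes, 0.0329 without a filter on low counts, and 0.0200 by DESeq2. Chga, a granule protein of most endocrine cells, had 0.37 ± 0.16, Cck 0.33 ± 0.15 and Gcg 0.31 ± 0.12. The list scores were 0.15 to 0.29 in cKO libraries 1, 2 and 4 but -0.053 in cKO library 3, against -0.28 to 0.052 in WT.

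Cytosolic ribosomal protein genes were higher for 45 of 48 members, by a small median of 0.15 (camera adjusted p = 8.65e-06, and 0.982 with an estimated correlation). Rps15 had 0.27 ± 0.14, Rps20 0.25 ± 0.13 and Rplp2 0.25 ± 0.14. Rps15 was at 0.15 and Rplp2 at 0.16 without cKO library 3, and at 0.075 and 0.080 without both libraries 3. These genes have many pseudogenes that can take reads. The score was 0.33 in cKO library 3, which also stood apart from the other libraries, -0.086 to 0.060 in the other cKO libraries and -0.26 to 0.054 in WT. The mean of 0.13 was 0.051 without cKO library 3, 0.064 without WT library 3, 0.039 with sample quality weights and -0.016, with the call lost, without both.

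Markers of T cells and intraepithelial lymphocytes, cells that lie between the epithelial cells, had higher point estimates for 18 of 21 members with a median of 0.37 (camera adjusted p = 0.0213, and 0.982 with an estimated correlation). Their scores varied within groups, from -0.98 to 0.80 in WT and from -0.44 to 1.05 in cKO, with cKO library 3 highest. Without that library the mean was -3.76e-05. Cd8b1, at 1.22 ± 1.17 and 2.88 ± 2.23 CPM, Cd3g, at 10.5 ± 5.02 and 15.4 ± 7.26 CPM, Lck, with a log2 fold change of 0.52 ± 0.41 (SE), and Ccl5, at 47.5 ± 31.7 and 75.5 ± 62.1 CPM, all overlapped between groups. Lck was at 0.30, 0.86 and 0.17 without WT library 2, WT library 4 and cKO library 3, Cd3g at 0.35, 0.85 and 0.25, and Ccl5 at 0.41, 1.22 and -0.061, against 0.67 for Ccl5 and 0.56 for Cd3g with all libraries. Cd8b1 went from 1.25 to 2.15 without WT library 4 and to 0.74 without cKO library 3. The list also lost its call without WT library 1 or 2 or cKO library 1, at means of 0.28, 0.20 and 0.28, with sample quality weights (0.25) and without both libraries 3 (0.0060). The mean of 0.36 grew to 0.81 without WT library 4, 0.62 without cKO library 2 and 0.61 without cKO library 4.

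Interferon response genes were lower for 24 of 30 members, with a median of -0.27 (camera adjusted p = 0.0165, and 0.982 with an estimated correlation). Ifit3b had -0.98 ± 0.42, Oas2 -0.89 ± 0.63 and the RNA sensor Ifih1 -0.28 ± 0.20, while the GTPase Gbp2 went the other way at 0.98 ± 0.50. Ifit3b was at -0.59 without WT library 3, Oas2 at -0.55 and -1.40 without cKO library 3 or 4, and Ifih1 at -0.45, -0.19 and -0.14 without cKO library 1, 2 or 3 and at -0.058 without both libraries 3. Scores ran from -0.59 to 0.51 in WT and from -0.87 to 0.37 in cKO. Leaving out any of WT libraries 2, 3 or 4 or cKO libraries 2 or 3 ended the call, at means of -0.22, -0.17, -0.11, -0.048 and -0.15, while the mean of -0.24 grew to -0.43 without WT library 1, -0.45 without cKO library 1 and -0.37 without cKO library 4. The call was also lost with sample quality weights (-0.12) and without both libraries 3 (-0.076), and the mean was -0.13 without a filter.

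**Figure D2:**
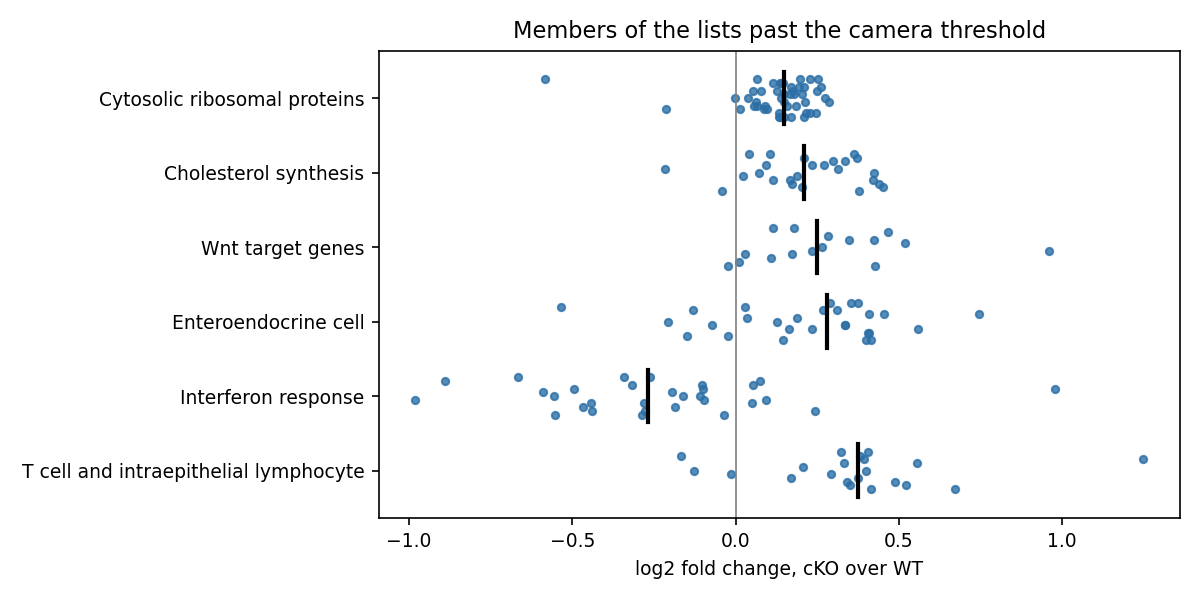
Log2 fold change (cKO over WT, horizontal axis) of each tested member of the 6 lists past the camera threshold. Each point is a gene and each black bar a list median, from -0.27 for interferon response genes to 0.37 for T cell markers; no member passed edgeR singly over all genes with the default filter and all libraries.

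The other 37 lists did not pass. Enterocyte markers had a median of -0.024 (12 higher, 14 lower; camera adjusted p = 0.786, with a test direction opposite to the mean of -0.055), goblet markers 0.019, Paneth markers 0.13 and tuft markers -0.14 (camera adjusted p = 0.0711). Enterocyte scores varied within groups, from -0.44 to 0.83 in WT, highest in WT library 3, and from -0.20 to 0.35 in cKO, highest in cKO library 1. Proliferation genes had a median of 0.056 and FoxO targets of -0.0040, of which Irs2 passed when adjusted over the list alone. Car4 did so among ion and water transport genes, and Ces1f among xenobiotic metabolism genes, whose median was -0.17. Glycolysis genes had a median of 0.0068, fatty acid oxidation genes of -0.059 and nuclear-encoded oxidative phosphorylation genes of -0.011.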

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

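The Xist test below was chosen after the Y-linked values were seen, and the length and GC correction was added after cKO library 3 was seen to stand apart. In 5 of 118 groups of 4 libraries, 1 library lay far from the other 3 relative to the range of the group, about the number that chance gives at 1 in 20.

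Tti1 was low in cKO library 1, at 25.3 CPM against 33.4 to 34.3 in the other cKO libraries, a gap of 0.895 of the range. Akt1s1 was high in cKO library 3, at 111 CPM against 79.3 to 81.3, a gap of 0.939. Akp3 was high in WT library 2, at 76.3 CPM against 47.0 to 49.6, a gap of 0.911. Dkk3 was high in cKO library 2, at 3.90 CPM against 1.78 to 1.99, a gap of 0.900.

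Ddx3y, a Y-linked helicase, was low in cKO library 3, at 26.0 CPM against 56.8 to 59.7 in the other cKO libraries, a gap of 0.915 of the range. The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty lay there at 0.458 to 0.547 of the mean of the other 7 libraries, a median log2 deviation of -0.91. This pattern was noticed in these data, so its size carries no test of chance. Cells from a female animal are argued against, since Xist, the transcript of the inactive X chromosome, was at 0.204 of the highest of the other libraries, with 6 counts. This library also had the strongest trend with transcript length and GC content, which made up 29.2% of the variance of its deviations against at most 4.04% in the others. Removing it left a median of -0.36, between the bounds set for and against this trend, so the trend may account for part of the deficit and the rest stays open. No other explanation was tested.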

How the results depend on the processing

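The count of 2 genes held with DESeq2-style and upper-quartile factors, with the stricter filter, and with length and GC trend removed. It was 10 without a filter, 8 with voom quality weights (4 at 2-fold), 41 with DESeq2 (22 at 2-fold), 0 with limma on log2(FPKM + 0.1) and on log2(FPKM + 1) (0 at 2-fold in both; Popdc3 3.03 and 1.41, Ces1f -1.22 and -1.17), 2 with limma on log2(FPKM + 0.1) without a filter, Popdc3 among them, and 4 without WT library 3 and cKO library 3. Leaving out 1 library gave 0 to 3 genes, at 2-fold too: 0 without WT library 1, 2 or 3, and 1 without WT library 4 or cKO library 1 or 4. The count of 6 lists ranged from 7 to 18 without 1 library (18 without WT library 3, 10 without cKO library 1 or 4, 11 without cKO library 3), and was 13 with voom weights, 0 with an estimated correlation, 0 by fry, 15 without both libraries 3 and 14 with length and GC trend removed.

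With the replicate number as a block the count was 0, and 0 at 2-fold, with Popdc3 at 3.62 and Ces1f at -1.23. Same-numbered libraries correlated at -0.11, 0.11, 0.15 and 0.14 in their deviations, so the numbers were not taken to pair all of them. Libraries 3 and 4 correlated best with their own number, but libraries 1 and 2 with the other of these numbers (0.15 and 0.12).

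Rictor kept its direction in all alternatives run (-0.67 to -0.25), and its adjusted p was never under 0.645. Of 876 values of named genes 12 changed sign. Mtor did so with voom weights (-0.016), without both libraries 3 (-0.051) and with length and GC trend removed (-0.054), Akt1s1 without both libraries 3 (-0.041) and with the trend removed (-0.012), and Ccl5 without both (-0.13). Leaving out 1 library gave Mtor -0.062 to 0.052 (below 0 without WT library 2 or cKO library 3), Mlst8 -0.11 to 0.034 (above 0 without WT library 2 or cKO library 2 or 4), and Ccl5 -0.061 (without cKO library 3) to 1.22. The ribosomal list turned without both libraries 3 (-0.016) and the T cell list without cKO library 3 (-3.76e-05, against up to 0.81 without WT library 4). The cause was not tested, apart from fewer libraries where some were left out. At these depths and this spread the simulation recovered 13.4% of 1.5-fold changes, so changes of that size mostly stay below the threshold. The simulation held more changed genes than the 2 called here, which eases the adjusted threshold, so its shares of recovered genes are upper guides.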

Other observations

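The following genes were called by DESeq2 but not by edgeR with all libraries and the default filter, and were chosen after their values were seen. Gsdmc2, Gsdmc3 and Gsdmc4, adjacent gasdermin genes on chromosome 15 between 63824346 and 63912297, were lower in cKO, with DESeq2 log2 fold changes of -1.25 ± 0.28, -1.44 ± 0.35 and -1.38 ± 0.27 (SE; DESeq2 adjusted p = 0.00800, 0.0184 and 0.000887). They are similar in sequence, so reads can be shared among them, and their edgeR adjusted p were 0.804, 0.921 and 0.630. S100g, the vitamin D-responsive calcium binding protein calbindin-D9k, was at 16.9 ± 4.87 CPM in WT and 54.9 ± 27.0 CPM in cKO (SD, n = 4 each; DESeq2 adjusted p = 0.000637, edgeR adjusted p = 0.727). It overlaps Ctps2 on the opposite strand. Cth, which makes cysteine from cystathionine, was at 112 ± 5.89 and 49.6 ± 19.6 CPM (DESeq2 adjusted p = 0.00479, edgeR adjusted p = 0.630). Nr0b2, a nuclear receptor of bile acid signalling, was at 2.13 ± 0.728 and 4.90 ± 0.752 CPM (DESeq2 adjusted p = 0.0126, edgeR adjusted p = 0.533), and Igfbp4, an IGF binding protein of crypt cells, with an edgeR log2 fold change of 0.80 ± 0.16 (DESeq2 adjusted p = 0.00943, edgeR adjusted p = 0.386). Cth, Nr0b2 and Igfbp4 passed edgeR when adjusted over their lists alone, and Igfbp4 was also called by edgeR without a filter and by voom with quality weights.

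Of the tests that follow, those on Popdc3 in a library left out, on T cell scores and on DESeq2 across splits were chosen after the result they address was seen, as were the length and GC correction and the allowance for spread in the 50-gene score.

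The 8 libraries can be split into 4 and 4 in 35 ways, and chance is not excluded for any of the counts. The edgeR count of 2 genes was reached by 3 splits, the real one included, with 8 genes in the highest other split, and the same held for the 2 genes changed 2-fold. The 6 lists were reached by all 35 splits, with 26 in the highest other split and a median of 16, so a count of lists from camera at its preset correlation does not set the genotypes apart from other groupings. The 41 genes of DESeq2 were reached by 8 splits, with 174 in the highest other. The splits with several times the real count point to structure among the libraries other than genotype. On the first principal component (26.5% of variance) cKO library 3 stood apart, and on the second (19.0%) WT library 3.

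The counting intervals of Rictor in cKO libraries 2 and 4 overlapped those of WT libraries 1 and 2. Removing the length and GC trend of each library left a gap of 0.063 on the log2 scale between the lowest WT and the highest cKO library, below the 0.3 set beforehand for that trend as the cause. The trend made up only 0.498% to 4.04% of the variance of deviations in cKO libraries 2 and 4 and WT libraries 1 and 2. A gap of 0.3 was therefore hard to reach, and missing it says little. For a wrong label, the test set beforehand placed each library between the WT mean (0) and the cKO mean (1) on 50 genes chosen without it. The lower of cKO 2 and 4 was cKO 4 at 0.489, just on the WT side, which met the criterion for a wrong label. However, WT library 3 lay at 0.880 and the libraries scattered by 0.452 about their own group, so this score does not decide. Over all genes cKO library 4 was nearest to WT library 4, at a chi-square per degree of freedom of 10.8. WT libraries 2 and 1 followed, at 19.2 and 19.7, ahead of its nearest cKO library, cKO library 2, at 20.6. By this measure cKO library 2 was itself nearest to cKO library 4. By correlation of log2 CPM, cKO library 2 was nearest to WT library 1 (0.9826, against 0.9816 with cKO library 4). A later test read 1 gene, Popdc3, which was called in fits without the library in question. It was 6.98 times the highest WT library in cKO 2 and 8.17 times in cKO 4. Popdc3 had been picked with these values in view, as the gene with the smallest p over all 8 libraries. This test therefore does not decide on a wrong label either. A wrong label stays open. So do retained transcript outside the deleted exons, unrecombined cells and most other cell types, all untested. T cell scores were -0.42 and -0.44 in cKO libraries 2 and 4, against 0.53 and 1.05 in cKO libraries 1 and 3. Myeloid scores were -0.011 and -0.22 against 0.29 and 0.48. Both argue against these cells as the source of the higher Rictor in cKO 2 and 4. B cell and endothelial scores did not split this way, and fibroblasts had too few tested members for a score.

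Spry4, Dusp4, Etv4 and Etv5, targets or feedback regulators of ERK signalling, were picked because all were higher in cKO, with a median log2 fold change of 1.11. With the T cell score as a covariate the median was 1.14, and with the length and GC trend removed it was 1.02, which argues against lymphocytes or that trend as the whole cause. A wider rise of such genes is a hypothesis, and 6 others listed before this test was run were Phlda1, Spry2, Dusp6, Ccnd1, Epha2 and Epha4. Their median was 0.20, with 4 higher and 2 lower. Ccnd1 is also in the Wnt list reported above. The values of the 6 were not kept unseen before this test, so they are not an independent set. Their fry p was 0.157, camera at its preset correlation gave 0.0302, and the exact permutation p of their score was 0.143, so whether the rise extends beyond the genes that drew attention cannot be told apart from chance with these libraries.

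Il7r, 2.71 Mb from Rictor on chromosome 15, was among the genes with small p (log2 fold change 1.88 ± 0.38 SE, edgeR adjusted p = 0.374). The only explanation tested for Il7r was DNA of another strain carried along with the floxed allele, read on the other genes within 10 Mb. Of 38 tested there 2 (5.26%) had an unadjusted edgeR p under 0.05, Oxct1 and the pseudogene Gm7666, against 3.88% elsewhere (Fisher's exact two-sided p = 0.659), which leaves it open at this number of genes. Gm7666 (chromosome 15, 6653923 to 6654741) lies closer to Rictor and was called by DESeq2 (log2 fold change 1.40 ± 0.36 SE, DESeq2 adjusted p = 0.0361), with overlapping groups.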
